A study of Mus musculus with 18 samples.

How the data were processed

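RNA was measured in 18 libraries of sorted brain macrophages from mice. The recipients were irradiated C57BL/6 mice, and the donor marrow carried Ms4a3-Cre, a Cre-dependent tdTomato reporter and a Cx3cr1-gfp allele. Ms4a3-Cre marks granulocyte-monocyte progenitors and their progeny, so that tdTomato and GFP together were taken as monocyte-derived, GFP without tdTomato as derived from haematopoietic stem cells (HSC) by another route, and cells with neither colour as host. Per the labels, cells were taken 32 weeks after transplantation and up to 100000 were sorted per library. Leptomeningeal cells were washed off the brain surface after collagenase digestion, and the remaining brain tissue was digested and cleared on Percoll for microglia. Actinomycin D was present during preparation, polyadenylated RNA was captured on oligo(dT) beads, and libraries were made by bulk MARS-seq, a 3' method with unique molecular identifiers (UMIs).

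The authors deposited 1 table of UMI counts per gene, together with scaled and log-transformed versions that were not used. The unscaled columns held whole numbers with a different total in each library. The labels give the mouse genome build mm10; the aligner, the counting program and any gene filter are not given in the sources used here. The table holds 13043 genes and 20 libraries; 2 libraries matched no described sample and entered no step. Gfp, tdTomato, Ms4a3 and the Y-linked genes of the fixed list are not in the table, so that the sort could not be checked on them. Nor could the share of cells that the label missed be checked. Origin of the donor cells here stands for the presence or absence of the label. The labels do not say that replicates are separate mice, so every p-value measures only the spread between these samples.

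The groups were host microglia, monocyte-derived microglia, HSC-derived microglia and monocyte-derived leptomeningeal macrophages with 4 libraries each, and HSC-derived leptomeningeal macrophages with 2. Total counts per library ran from 154727 to 2440234. A count of 3 in a library corresponded to between 1.05 and 23.1 CPM, the counts scaled to library size. Counting intervals and floors cover counting error only.

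Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), which left 10597. Libraries were scaled by TMM, and all CPM are scaled in that way. All 18 libraries were fitted in 1 quasi-likelihood (QL) model with robust dispersion and a coefficient per group; the common biological coefficient of variation was 0.16. The 7 comparisons were each donor-derived microglia group against host microglia, both donor-derived microglia groups against each other, both donor-derived leptomeningeal groups against each other, leptomeningeal macrophages against microglia within each origin, and the interaction of origin with compartment. Tests were two-sided edgeR QL tests, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05; a gene past it is called higher or lower. Levels are given as group means ± SD of CPM, and changes as log2 fold changes. Against a group with no count, the fold is a lower bound that takes 3 counts over the group; with 1 to 3 counts in a group, the ratio of counts is given with its 95% exact (Clopper-Pearson) interval. Gene positions are those of GENCODE vM21.

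The comparisons, the groups, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. The rule named, for each comparison of 4 against 4 libraries, the 10 highest and the 10 lowest called genes by log2 fold change with at least 50 CPM in the higher group and no overlap between the libraries of both groups. For the other comparisons it named 5 in each direction. For the interaction there was no overlap condition. It added up to 4 members of each list with the smallest p, and a fixed set that included Cx3cr1, P2ry12, Tmem119, Sall1, Ms4a7, Apoe, Clec12a, Mrc1, Ccr2 and Ly6c2. Predicted genes and pseudogenes were left out of the top genes.

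The 27 lists cover homeostatic microglia, bone marrow-derived brain macrophages as described in other studies, border-associated macrophages, disease-associated microglia, MHC class II and MHC class I antigen presentation, the type I interferon response, inflammatory cytokines and NF-kB targets, immediate early and heat shock genes, p53 targets and irradiation response, the cell cycle, TGF-beta signalling, cholesterol synthesis and efflux, and complement, Fc and phagocytic receptors. Markers of other cells cover monocytes, neutrophils and myeloid progenitors, dendritic cells, T and NK cells, B cells, neurons, oligodendrocytes, astrocytes, endothelial cells, leptomeningeal fibroblasts and mural cells, and erythroid cells. The cytosolic ribosomal proteins and the sex chromosome genes were added as checks of the libraries. For each list the number of called members is given over all genes and adjusted over the list alone. The 26 lists with at least 5 tested members were tested against all other genes with limma's camera on voom values, with a preset correlation of 0.01, which gave 182 list tests over the 7 comparisons, adjusted within each comparison. Camera was repeated with a correlation estimated from the data, and fry, which tests a list without comparing it with other genes, was run beside it. List medians plotted in the heat map set members with no count on a side to their bound and leave out members at or under 3 counts on both sides.

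The pipeline was tested on simulated data with 100 genes changed by a log2 change of 1 and 100 by 2. The depths and spread were those of these libraries, with 1 mean per gene taken over all of them. At a log2 change of 2, 91% were recovered for monocyte-derived against host microglia, 86% for HSC-derived against host microglia, 83% between the donor-derived microglia, 72% between the leptomeningeal groups, 91% and 59% between compartments in monocyte-derived and HSC-derived cells, and 59% for the interaction. At a log2 change of 1 the shares were 69%, 51%, 50%, 22%, 70%, 17% and 8%. Between 2 and 12 of 10372 unchanged genes were called, and 0 of 20 lists of unchanged genes. Genes were drawn independently of each other, so the list tests were not tried under correlation between genes. No simulated library differed in make-up from the others of its group, so the shares do not cover such differences either.

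Alternatives were DESeq2 size factors, no gene filter, a filter at 10 CPM, a model of only the libraries compared, limma-voom with quality weights, DESeq2 1.42.0, a fold change of at least 2, a block for the replicate number, and each library left out in turn. A model without the 3 libraries with under 320000 counts (HSC-derived microglia replicates 3 and 4 and HSC-derived leptomeningeal macrophages replicate 2, called the 3 shallow libraries) and counts thinned to 150000 per library were chosen after seeing the data. For comparisons of 4 against 4 libraries, all 35 splits of the 8 libraries were refitted. The overlap of changes against the shared host libraries was compared with splits of the host libraries into 2 and 2, so that each donor-derived group had its own, and with 20 simulations in which all microglia groups were drawn from the host means and shared the drawn host libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.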

Results

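Expression was compared between 5 groups of sorted brain macrophages from bone marrow chimaeras, 32 weeks after irradiation and transplantation. Host microglia, monocyte-derived microglia, HSC-derived microglia and monocyte-derived leptomeningeal macrophages had 4 libraries each, and HSC-derived leptomeningeal macrophages had 2. Total UMI counts were 1230127, 1908401, 2440234 and 1303688 for host microglia replicates 1 to 4, and 1507199, 1072911, 1299705 and 1120421 for monocyte-derived microglia. They were 691691, 692884, 264795 and 317872 for HSC-derived microglia, 1452760, 1066281, 1809700 and 1586391 for monocyte-derived leptomeningeal macrophages, and 648266 and 154727 for HSC-derived leptomeningeal macrophages. The first principal component of log2 CPM held 38.5% of the variance and the second 20.6%.

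The 3 shallow libraries stood apart from the others of their groups. In HSC-derived microglia, ribosomal protein transcripts made up 14.1% and 13.4% of counts in replicates 3 and 4, against 8.68% and 8.89% in replicates 1 and 2. Apoe made up 18.5% and 16.5% in the shallow pair against 11.4% and 9.17% in the deeper pair. Transcripts of ribosomal pseudogenes made up 0.787% and 0.748%, against 0.15% and 0.152%. The shallow HSC-derived leptomeningeal library held 19.1% ribosomal protein and 0.882% ribosomal pseudogene transcripts, against 15.2% and 0.227% in the other library of that group. No label gives a batch for these libraries, and each belongs to an HSC-derived group.

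**Figure D1:**
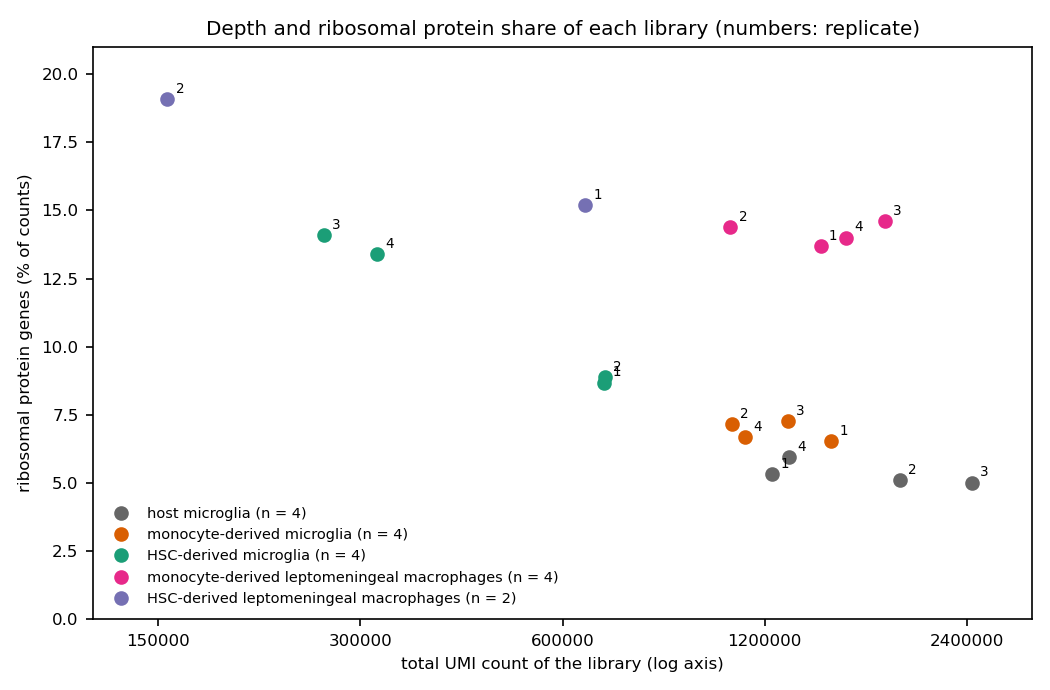
Total UMI count of each library (log axis) against the share of counts from ribosomal protein genes in percent; each point is a library, coloured by group and numbered by replicate. The 3 libraries under 320000 counts hold 14.1%, 13.4% and 19.1% ribosomal protein transcripts.

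The comparison of monocyte-derived with host microglia asked how donor cells with the Ms4a3 fate label differed from resident microglia in the same compartment. Monocyte-derived microglia expressed Ms4a7, a membrane protein of the MS4A family, at 780 ± 30.5 CPM (SD, n = 4) against 6.05 ± 4.41 in host microglia, and Clec12a, an inhibitory C-type lectin receptor, at 345 ± 6.79 against 1.32 ± 1.26. Apoe, which encodes the lipid carrier apolipoprotein E, rose from 3370 ± 256 to 84900 ± 4820 CPM. Sall1, a transcription factor of microglial identity, fell from 326 ± 10.7 to 31.4 ± 8.59 CPM. The purinergic receptor gene P2ry12 and the microglial surface marker Tmem119 remained abundant, at 1580 ± 115 and 1060 ± 36.6 CPM, below the 4690 ± 513 and 2610 ± 405 of host microglia. Cdkn1a, which encodes the p53-induced cell cycle inhibitor p21, fell from 2070 ± 265 in host cells to 186 ± 10.4.

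Of 10597 genes, 3201 passed the edgeR test (30.2%), 1604 higher and 1597 lower in monocyte-derived microglia. Of the 35 splits of these 8 libraries into 4 and 4 only the real one called this many, and the highest other count was 0. Among the 10 highest, Gdf3, a ligand of the TGF-beta superfamily, had 120 ± 23.1 CPM, a count ratio of 483 (95% interval 133 to 3990). Cmah, an enzyme of sialic acid metabolism, had a ratio of 440 (78.5 to 17400). The lectin-like receptor gene Klra2 had a ratio of 272 (74.7 to 2250), and the aryl hydrocarbon receptor gene Ahr one of 202 (55.4 to 1670). Cd93, Ms4a14, Ctse, which encodes cathepsin E, and Plbd1 rose by log2 changes of 7.41, 7.36, 7.27 and 6.48. The 10 lowest included the genes of the tetraspanin Upk1b (log2 change -4.41), the melanosome transport protein Mlph (-4.02), the transcription factor Sall3 (-3.87), Mymk (-3.85), the actin-bundling protein Fscn1 (-3.67), the adenylate kinase Ak1 (-3.65) and the junctional protein Jam2 (-3.50). Enpp2 and Ttr, both abundant in choroid plexus epithelium, had 188 ± 48.8 and 2520 ± 567 CPM in host microglia and 1.94 ± 1.83 and 46.3 ± 73.8 in monocyte-derived microglia.

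Homeostatic microglia genes fell as a list, with 20 of 26 tested members lower and 1 higher over all genes, and 20 and 2 adjusted over the list alone (camera adjusted p = 2.7e-14, and adjusted p = 0.0413 with an estimated correlation). Sall1 had a log2 change of -3.38. The bone marrow-derived brain macrophage list rose, with 18 higher and 1 lower of 20, the same counts adjusted over the list alone (camera adjusted p = 1.78e-21, and adjusted p = 0.0012 with an estimated correlation). Border-associated macrophage genes rose too, with 23 higher and 3 lower of 28, unchanged when adjusted over the list alone (1.26e-11, and adjusted p = 0.0404 with an estimated correlation). Among them the mannose receptor gene Mrc1 went from 26.6 ± 2.11 to 597 ± 29.2 CPM, and the platelet factor gene Pf4 from 4.82 ± 0.87 to 407 ± 26. Cx3cr1 fell by 1.17 on the log2 scale, to 1730 ± 108 CPM, in cells from donors that carried a gfp allele of this gene.

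MHC class II genes, which present peptides to CD4 T cells, were higher for 6 and lower for 2 of 12, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.000258, but adjusted p = 0.234 with an estimated correlation). H2-Eb1 rose from 15.5 ± 4.99 to 773 ± 168 CPM and the invariant chain gene Cd74 from 49.5 ± 2.52 to 1220 ± 244. The type I interferon list had 19 of 34 members higher, 24 adjusted over the list alone (camera adjusted p = 2.82e-09, adjusted p = 0.145 with an estimated correlation). Ifi204, an interferon-inducible DNA sensor gene, rose to 186 ± 6.9 from 39.5 ± 8.23 CPM. Of 26 inflammatory genes, 11 were higher and 4 lower, 13 and 6 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.75 with an estimated correlation). The chemokine gene Cxcl16 rose by a log2 change of 1.89. Of 24 p53 targets, 12 were lower and 3 higher, 13 and 3 adjusted over the list alone (camera adjusted p = 0.00067, adjusted p = 0.167 with an estimated correlation). Phlda3, an inhibitor of Akt signalling, and Bbc3, which encodes the pro-apoptotic protein PUMA, fell from 48.7 ± 1.83 and 48.3 ± 8.83 to 2.77 ± 1.38 and 11.6 ± 3.63 CPM. Sesn1, another p53 target, moved the other way, with a log2 change of 1.44. Complement, Fc and phagocytic receptor genes had 6 higher and 11 lower of 26, 6 and 12 adjusted over the list alone (camera downward, adjusted p = 0.0264, adjusted p = 0.327 with an estimated correlation); their median log2 change was -0.29 and their mean 0.11. Ribosomal protein genes had 16 of 62 higher by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.000126, adjusted p = 0.783 with an estimated correlation).

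Markers of other cells moved with this comparison. T and NK cell genes were higher for 15 of 16, as also when adjusted over the list alone (camera adjusted p = 1.27e-05, adjusted p = 0.167 with an estimated correlation). Cd8a was at 22.9 ± 5.76 against 4.31 ± 0.771 CPM and Trac at 9.54 ± 0.932 against 2.87 ± 1.63. Monocyte genes were higher for 12 of 17, as also when adjusted over the list alone (camera adjusted p = 2.99e-05, adjusted p = 0.103 with an estimated correlation). Ccr2 was at 48 ± 6.98 against 8.89 ± 2.27 and Ly6c2 at 16.9 ± 4.44 against 1.16 ± 0.756. The astrocyte list was not called (camera adjusted p = 0.211), with 2 of 8 lower by both adjustments, over all genes and adjusted over the list alone; its member Slc1a3, a glutamate transporter gene, fell from 187 ± 21.7 to 20.9 ± 2.59 CPM. Other lists did not pass camera. Counts over all genes, then adjusted over the list alone, were 7 higher and 6 lower, then 8 and 6, of 22 disease-associated microglia genes (camera adjusted p = 0.753). They were 4 and 1 both times of 19 MHC class I genes (camera adjusted p = 0.321), 3 and 1 both times of 25 immediate early and heat shock genes (camera adjusted p = 0.504), and 6 and 4, then 6 and 5, of 21 TGF-beta genes (camera adjusted p = 0.957). The median of the TGF-beta list was -0.13 and its mean 0.07. Cholesterol genes had 4 and 4 both times of 19 (camera adjusted p = 0.937), with a median of -0.19 and a mean of 0.01. Neutrophil genes had 2 and 1, then 3 and 1, of 9 (camera adjusted p = 0.44), and dendritic cell genes 4 and 1, then 6 and 1, of 9 (camera adjusted p = 0.297). Endothelial genes had 3 and 3 both times of 6 (camera adjusted p = 0.937), and fibroblast and mural genes 1 and 1 both times of 8 (camera adjusted p = 0.957), with a median of -0.17 and an upward test. With both adjustments giving the same count, 1 of 16 cell cycle genes was lower (camera adjusted p = 0.937), 1 of 5 neuron genes higher (camera adjusted p = 0.297), 1 of 9 oligodendrocyte genes lower (camera adjusted p = 0.998, median 0.32), and no B cell (camera adjusted p = 0.574) or erythroid (camera adjusted p = 0.957) gene passed. The only sex chromosome gene tested, Xist, had 75.4 ± 9.91 CPM against 47.3 ± 5.48. The calls of the genes named for this comparison held in every alternative run that tested them. A gene that an alternative did not test was not counted as lost, and the thinned counts left 4516 genes to test.

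**Figure D2:**
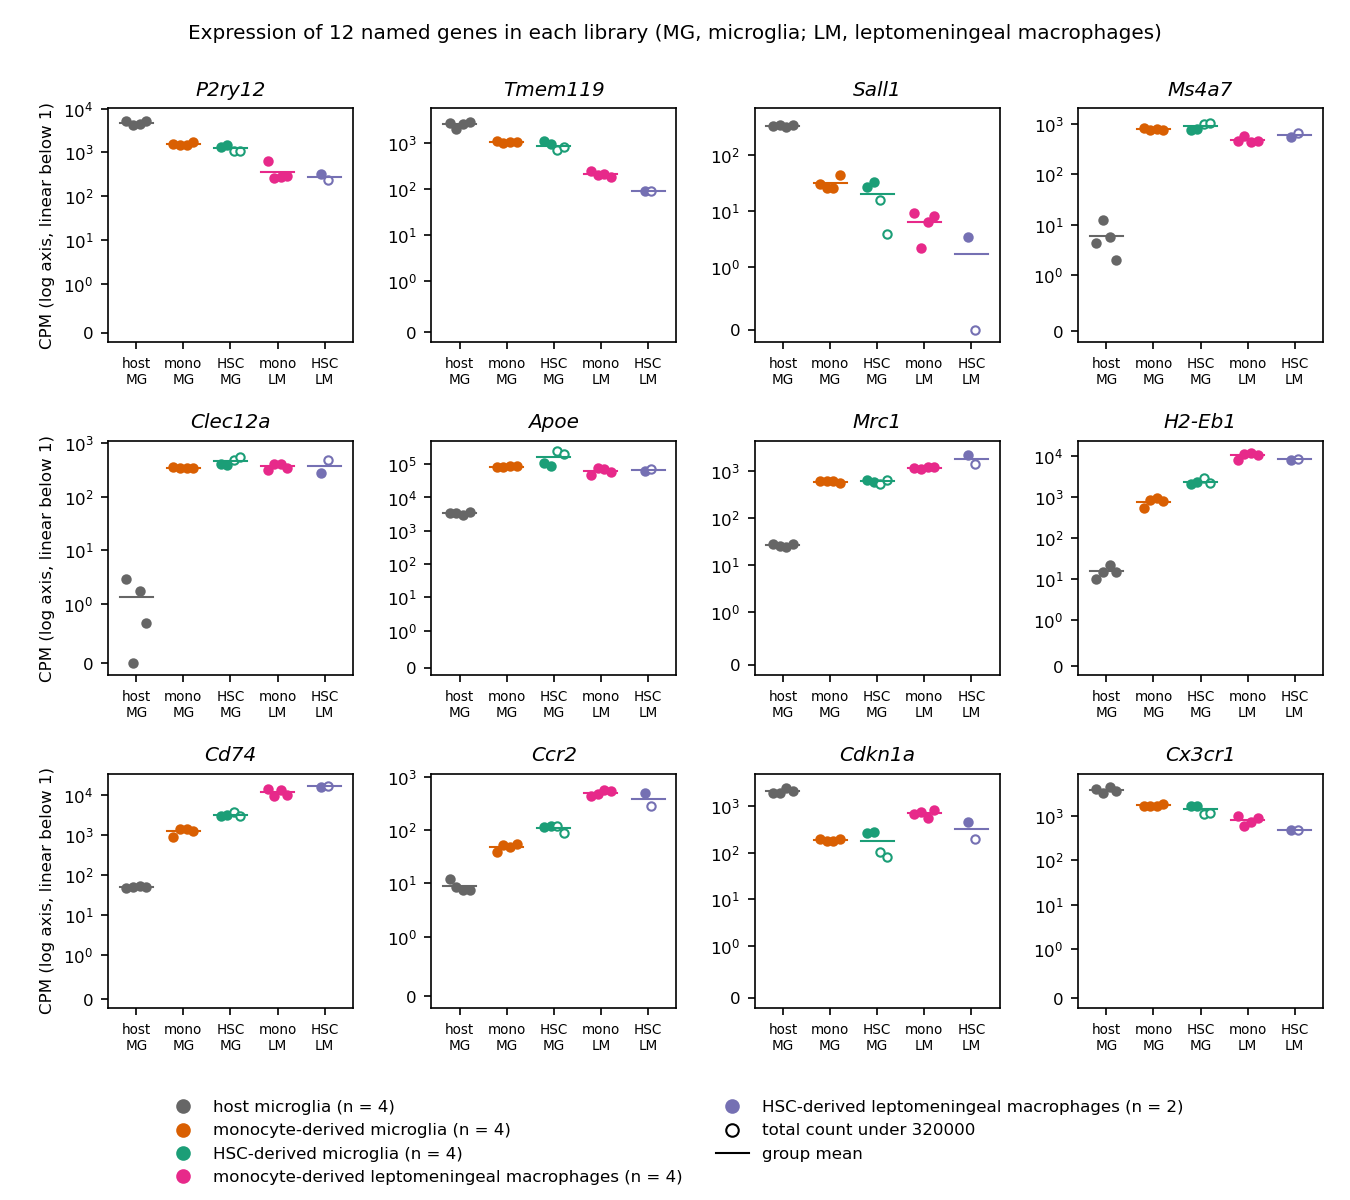
Expression of 12 named genes in CPM (log axis, linear below 1) in each library; points are libraries, bars are group means, and open points are the 3 libraries under 320000 counts. Sall1 averages 326 CPM in host microglia and 31.4 in monocyte-derived microglia, and H2-Eb1 averages 773 CPM in monocyte-derived and 2360 in HSC-derived microglia.

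The comparison of HSC-derived with host microglia asked the same question for donor cells without the Ms4a3 fate label. HSC-derived microglia had Ms4a7 at 885 ± 143 CPM, Clec12a at 459 ± 71.6, Mrc1 at 606 ± 57 and Apoe at 164000 ± 77300 (n = 4), all far above host microglia. H2-Eb1 reached 2360 ± 370 CPM against 15.5 ± 4.99 and Cd74 3180 ± 370 against 49.5 ± 2.52. Sall1 fell to 19.8 ± 12.9 CPM, P2ry12 to 1250 ± 226, Tmem119 to 897 ± 170 and Cx3cr1 to 1410 ± 294. Cdkn1a fell to 179 ± 103 CPM from 2070 ± 265.

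Of 10597 genes, 3114 passed (29.4%), 1723 higher and 1391 lower. Of the 35 splits of these 8 libraries only the real one called this many, and the highest other count was 1. A chance division is not excluded by this, since 1 of 35 is the smallest share such splits can give. The highest included the chemokine gene Ccl8, with a count ratio of 390 (95% interval 106 to 3240), the vanin gene Vnn3 with 484 (85.2 to 19300), the scavenger receptor gene Cd36 with 388 (67.9 to 15500), Klra2 with 320 (87.1 to 2670) and Gdf3 with 265 (72 to 2220). Plbd1 and Ctse rose by log2 changes of 7.27 and 7.32. The lowest included Sall3 (-4.45), Mymk (-4.39), the glycosyltransferase gene B3galt5 (-4.25), Upk1b (-4.14), Mlph (-4.11), Enpp2 (-4.10), the neuron navigator gene Nav3 (-4.08) and the lipase gene Liph (-4.05). Nhlh2, a neuronal transcription factor gene, averaged 8080 ± 9410 CPM, which came from the shallow replicates 3 and 4 alone, and without the 3 shallow libraries its log2 change was 1.05 (adjusted p = 0.959). Ttr, at 198 ± 217 against 2520 ± 567 CPM, was not called without the shallow libraries (adjusted p = 0.107), with a log2 change of -3.44 against -3.61 with all libraries.

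Homeostatic microglia genes fell, with 22 of 26 lower, and 23 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.93e-18, and adjusted p = 0.018 with an estimated correlation). The bone marrow-derived list rose with 18 higher and 1 lower of 20, 19 and 1 adjusted over the list alone (9.4e-25, and adjusted p = 0.000607 with an estimated correlation). Border-associated macrophage genes rose with 21 higher and 2 lower of 28, 22 and 3 adjusted over the list alone (3.68e-15, and adjusted p = 0.0147 with an estimated correlation). Pf4 was among them at 621 ± 199 CPM. MHC class II genes were higher for 8 and lower for 1 of 12, the same adjusted over the list alone (camera adjusted p = 3.18e-08, adjusted p = 0.0848 with an estimated correlation). H2-Aa had 3840 ± 494 against 38.1 ± 11.9 CPM. Of 34 interferon genes, 23 were higher, 25 adjusted over the list alone (camera adjusted p = 3.95e-11, adjusted p = 0.0908 with an estimated correlation). Bst2, which encodes the virus-tethering protein tetherin, had 2490 ± 924 against 467 ± 54.7 CPM and Ifi204 218 ± 56.6. Inflammatory genes were higher for 14 and lower for 5 of 26, 14 and 7 adjusted over the list alone (camera adjusted p = 0.00541, adjusted p = 0.54 with an estimated correlation). Cxcl16 rose by a log2 change of 2.03. Of 24 p53 targets, 9 were lower and 2 higher by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.00109, adjusted p = 0.145 with an estimated correlation). Phlda3 fell to 0.708 ± 1.42 CPM, a count ratio of 46.2 (12.7 to 383), while Sesn1 rose by a log2 change of 1.14.

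Beside these, ribosomal protein genes were higher for 60 of 62, 61 adjusted over the list alone (camera adjusted p = 1.5e-33, adjusted p = 0.139 with an estimated correlation), with a median log2 change of 1.47. Without the shallow libraries 56 were called and the median was 0.82; Rps24 had 3820 ± 1290 against 852 ± 158 CPM. Disease-associated microglia genes were higher for 10 and lower for 5 of 22, 13 and 6 adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.311 with an estimated correlation). MHC class I genes were higher for 10 and lower for 2 of 19, 11 and 3 adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.386 with an estimated correlation). Both calls were lost without the shallow libraries (0.0681 and 0.0906), while the immediate early (camera adjusted p = 0.00222) and dendritic cell (0.0205) lists were called higher there. Monocyte genes were higher for 9 and lower for 1 of 17 by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.0978 with an estimated correlation), with Ccr2 at 109 ± 15.3 CPM. Ly6c2, at 7.38 ± 4.71 against 1.16 ± 0.756 CPM, was not called without HSC-derived microglia replicate 2 (adjusted p = 0.0971). T and NK cell genes were higher for 5 of 16, 6 adjusted over the list alone (camera adjusted p = 0.0363, adjusted p = 0.54 with an estimated correlation). Leaving out single libraries also ended the calls of Nhlh2 (each host library, or HSC-derived microglia replicate 4) and of Ttr (each host library, or HSC-derived microglia replicates 2, 3 or 4).

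Genes called in both donor-derived groups against host microglia had the same direction in both. The overlap was 2067 genes with the same direction, 1021 higher and 1046 lower, with 0 in opposite directions, where independent calls of these numbers would share 470. Across 10597 genes the log2 changes had a Pearson correlation of 0.814; genes are not independent replicates. Both comparisons share the host libraries, which by itself raises the overlap. With the host libraries split so that each donor-derived group had its own 2, the 6 splits gave between 1404 and 1446 shared genes and correlations from 0.743 to 0.765, where independent calls would share 232 to 249. In 1 of these splits 2 genes were called in opposite directions, and in the others 0. In 20 simulations of unchanged groups with shared host libraries, correlations ran from 0.282 to 0.369; with at most 1 gene called in either comparison, their overlap of 0 does not measure what sharing adds to the count.

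**Figure D3:**
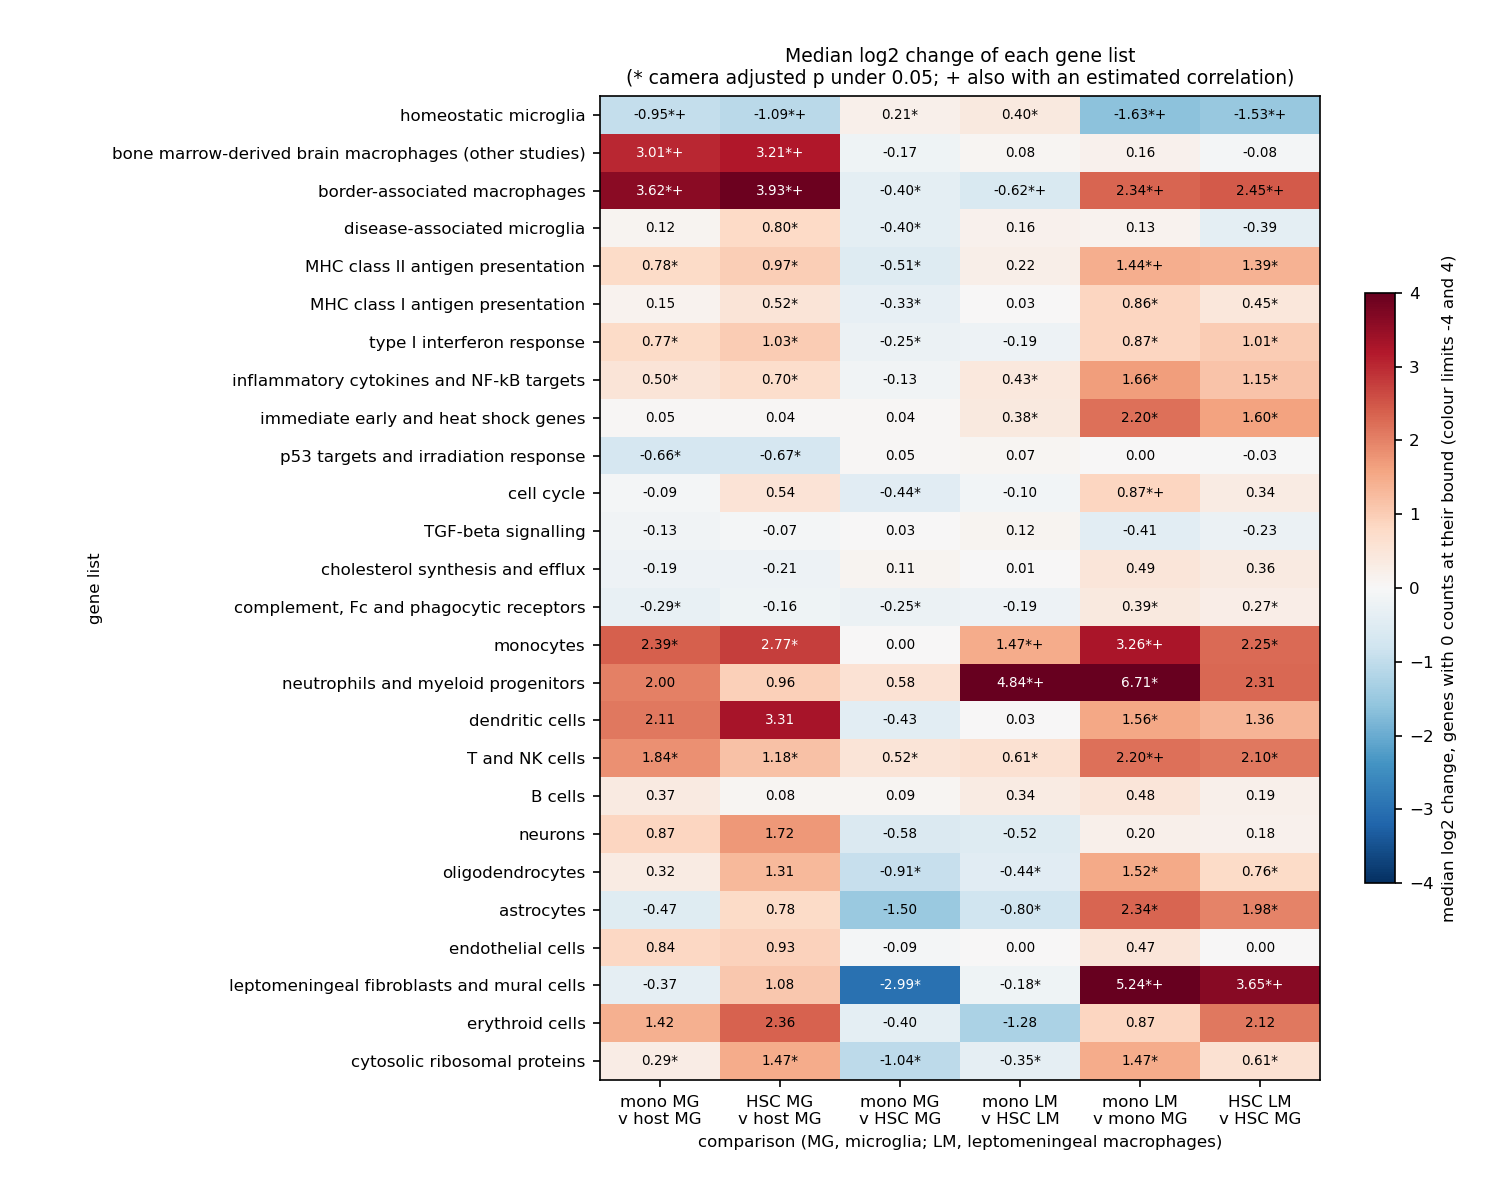
Median log2 change of each gene list (vertical axis) in 6 comparisons (horizontal axis), with members without counts on a side at their bound; the colour scale runs from -4 to 4, an asterisk stands for a camera adjusted p under 0.05 and a plus for a call that holds with an estimated correlation. Homeostatic microglia genes have medians of -0.95 and -1.09 in donor-derived against host microglia, and -1.63 and -1.53 in leptomeningeal macrophages against microglia.

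The direct comparison of monocyte-derived with HSC-derived microglia asked whether donor-derived cells of the same compartment differed with the fate label. Most named microglial and donor-cell markers did not pass the test, and 4 MHC class II genes differed whichever library was left out. H2-Eb1 was lower in monocyte-derived microglia, at 773 ± 168 CPM against 2360 ± 370 (n = 4 each, log2 change -1.61, adjusted p = 2.32e-05). H2-Ab1, at 1380 ± 325 against 3830 ± 359, H2-Aa, at 1350 ± 312 against 3840 ± 494, and Cd74, at 1220 ± 244 against 3180 ± 370, were lower too. The chemokine receptor gene Ccr2 had 48 ± 6.98 against 109 ± 15.3 CPM (adjusted p = 0.000517), and the coagulation factor gene F13a1 45.8 ± 7.2 against 104 ± 22. Vcam1, an adhesion molecule gene, was higher in monocyte-derived microglia at 679 ± 82.2 against 361 ± 125 CPM, as was Wasl, an actin regulator gene, at 54.6 ± 5.89 against 23.5 ± 3.02.

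The MHC class II list fell with 4 of 12 lower, 7 adjusted over the list alone (camera adjusted p = 2.04e-13, adjusted p = 0.0544 with an estimated correlation). H2-Eb1, H2-Ab1, H2-Aa, Cd74, F13a1 and the ribosomal gene Rplp2 were called whichever library was left out and also without the 3 shallow libraries. H2-Aa, H2-Ab1 and H2-Eb1 lie together on chromosome 17 (from 34282744 to 34287823, 34257689 to 34269419 and 34305867 to 34316674), and Cd74 lies on chromosome 18. Disease-associated microglia genes had 2 of 22 lower, 7 adjusted over the list alone (camera adjusted p = 2.46e-06, adjusted p = 0.0654 with an estimated correlation). They were Lgals3, which encodes galectin-3, at 52.7 ± 13.3 against 116 ± 36.8 CPM, and Cd52, at 557 ± 35.3 against 947 ± 201. Without the 3 shallow libraries 1 disease-associated gene was lower, with a list median of -0.19 (camera adjusted p = 0.00073). Border-associated macrophage genes had 5 of 28 lower, and 10 lower and 2 higher adjusted over the list alone (camera adjusted p = 3e-04, adjusted p = 0.313 with an estimated correlation). Without the 3 shallow libraries 2 were lower, with a list median of -0.13 (camera adjusted p = 0.0032). The chemokine gene Ccl8 was at 27.4 ± 3.08 against 147 ± 108 and the lectin gene Mgl2 at 13.4 ± 6.07 against 51.8 ± 16.5. Interferon genes had 3 of 34 lower, the same adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.513 with an estimated correlation), Ifi27l2a and Ifitm3 among them. Of 16 cell cycle genes none passed over all genes and 4 were lower adjusted over the list alone (camera adjusted p = 0.000265, adjusted p = 0.0544 with an estimated correlation).

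Ribosomal protein genes made up 50 of the 187 lower calls, 50 of 62 in the list, 60 adjusted over the list alone (camera adjusted p = 6.24e-66, adjusted p = 0.0544 with an estimated correlation) and a median log2 change of -1.04. Rpl35, Rps23, Rpl37a, Rps4x, Fau and Rps16 were among the 10 lowest genes, with log2 changes of -2.10, -2.05, -1.92, -1.81, -1.80 and -1.66. They moved with the 3 shallow libraries. Without these, 11 ribosomal protein genes were lower and the list's median was -0.44 (camera adjusted p = 4.06e-49), Rpl37a had a log2 change of -0.59, and Apoe went from -0.95 (adjusted p = 0.0307) to -0.22 (0.798). Markers of other cells moved with the same libraries. Oligodendrocyte genes had 1 of 9 lower, 4 adjusted over the list alone (camera adjusted p = 0.00274, adjusted p = 0.328 with an estimated correlation). The 1 was Ptgds, which encodes prostaglandin D synthase, at 34.3 ± 7.35 against 305 ± 268 CPM. Fibroblast and mural genes had 1 of 8 lower, 2 adjusted over the list alone (0.00413, adjusted p = 0.328 with an estimated correlation). Neither list was called without the shallow libraries (0.284 each).

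Levels of Mrc1, at 597 ± 29.2 against 606 ± 57 CPM, Ms4a7 and Clec12a did not differ by the test (adjusted p = 0.969, 0.705 and 0.25), nor did P2ry12 (0.464), Sall1 (0.579), Tmem119 (0.546), Cx3cr1 (0.445) or Ly6c2 (0.195). As a list, homeostatic microglia genes were slightly higher, with a median log2 change of 0.21 and no member called over all genes or adjusted over the list alone (camera adjusted p = 0.00274, adjusted p = 0.365 with an estimated correlation, and 0.153 without the shallow libraries). MHC class I genes had no call over all genes, and 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00471, adjusted p = 0.351 with an estimated correlation). Complement, Fc and phagocytic receptor genes had no call by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.328 with an estimated correlation). T and NK cell genes were the only other list called higher, with no member over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00658, adjusted p = 0.365 with an estimated correlation). Without the shallow libraries the MHC class I (0.195), interferon (0.614), complement (0.0521) and T and NK cell (0.15) lists were not called, while the inflammatory (3.89e-12), immediate early (1.54e-06) and dendritic cell (2.11e-05) lists were called lower.

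By the edgeR test 200 of 10597 genes passed (1.89%), 13 higher and 187 lower, with 1639 at an unadjusted p under 0.05. The real split was the only 1 of 35 to call this many, and the highest other count was 0. Without the 3 shallow libraries 50 passed, 3 higher and 47 lower, of which 29 were among the 200. The count was 33 without HSC-derived microglia replicate 3, 31 without replicate 4, 555 without replicate 1 and 525 without replicate 2. It was 49, 84, 102 and 69 without monocyte-derived microglia replicates 1, 2, 3 and 4. Of the other genes named here, Lgals3 lost its call without HSC-derived microglia replicate 3 (0.0521), and Vcam1, Wasl and Ccr2 kept theirs whichever library was left out. Apoe (0.213 and 0.182), Ptgds (0.169 and 0.182), Ccl8 (0.182 and 0.19), Mgl2 (0.0916 and 0.11), Cd52 (0.0789 and 0.173), Ifi27l2a (0.116 and 0.114), Ifitm3 (0.156 and 0.169), Rpl35 (0.118 and 0.123), Rps23 (0.137 and 0.144), Rpl37a (0.118 and 0.136), Rps4x (0.119 and 0.123), Fau (0.0789 and 0.0784) and Rps16 (0.112 and 0.123) lost theirs without replicate 3 or 4 of HSC-derived microglia. Most of these were also lost without a single monocyte-derived microglia library.

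The comparison of monocyte-derived with HSC-derived leptomeningeal macrophages asked about origin at the brain surface, with 4 libraries against 2. Neutrophil granule genes were seen in the monocyte-derived cells. Ngp, which encodes neutrophilic granule protein, had 344 ± 143 CPM and the cathelicidin gene Camp 328 ± 107, with 0 counts of either in the HSC-derived libraries, so that they were at least 81.4-fold and at least 76-fold higher. The lactoferrin gene Ltf was at least 20.1-fold higher, and S100a8, a calgranulin gene, had a count ratio of 139 (95% interval 38.5 to 1150). The monocyte gene Ly6c2 had 138 ± 32.8 against 39 ± 0.704 CPM, and Ace, at 42.3 ± 11.3 CPM, was at least 9.82-fold higher. HSC-derived cells had more Mgp, which encodes matrix Gla protein (81.5 ± 28.1 against 10.8 ± 3.66 CPM), Cd163, a haemoglobin scavenger receptor gene (474 ± 299 against 219 ± 32), Folr2, a folate receptor gene (659 ± 4.4 against 373 ± 78.1), Cd209g (145 ± 42.2 against 68.7 ± 1.69), the cytokine gene Tslp (97.3 ± 17.8 against 32.7 ± 5.85), the respiratory chain gene Ndufc1 (88.7 ± 5.68 against 40.5 ± 3.55) and the phospholipid transfer protein gene Pltp (947 ± 402 against 440 ± 79.8).

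Of 9 neutrophil and progenitor genes 4 were higher, 7 adjusted over the list alone (camera adjusted p = 1.93e-12, and adjusted p = 0.0235 with an estimated correlation). The median log2 change was 7.62 as fitted and 4.84 with the 4 members without counts on a side at their bound. Monocyte genes had 3 of 17 higher, 8 adjusted over the list alone (4.34e-08, and adjusted p = 0.0235 with an estimated correlation). Hp was among them with a count ratio of 31.1 (5.52 to 1230). Border-associated macrophage genes had 3 of 28 lower, and 12 lower and 1 higher adjusted over the list alone (5.34e-16, and adjusted p = 0.0213 with an estimated correlation). The median log2 change of this list was -0.78 without the shallow libraries, which left 1 HSC-derived library. Homeostatic microglia genes had 1 of 26 higher, Tmem119, and 7 adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.431 with an estimated correlation). Immediate early genes (camera adjusted p = 5.45e-06), inflammatory genes (0.00051) and T and NK cell genes (0.000409) tested higher, with no member called over all genes and 1, 1 and 2 higher adjusted over the list alone, beside 1 inflammatory gene lower. With an estimated correlation, adjusted p = 0.431, 0.47 and 0.431. Ribosomal protein (1.9e-08), oligodendrocyte (0.00453), astrocyte (0.0155) and fibroblast genes (0.0246) tested lower; 1 fibroblast gene, Mgp, was called over all genes, and adjusted over the list alone 1 ribosomal, 1 astrocyte and 1 fibroblast gene were called. With an estimated correlation, adjusted p = 0.525 for the ribosomal list and 0.431 for the other lists, and without the shallow libraries the oligodendrocyte (0.0612), astrocyte (0.113), fibroblast (0.122), inflammatory (0.923) and immediate early (0.113) calls were lost. Igkc, an immunoglobulin light chain gene of B cells, had 389 ± 215 against 7.73 ± 10.9 CPM and was not called (adjusted p = 0.078).

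By the edgeR test 32 genes passed (0.302%), 17 higher and 15 lower, with 1159 at an unadjusted p under 0.05. The balance moved with the method, to 3 higher and 15 lower with limma-voom. Without the 3 shallow libraries, which left a single HSC-derived library assumed to vary like the other groups, 72 passed, 25 of them among the 32. The count was 90 without HSC-derived replicate 1 and 12, 4 higher and 8 lower, without replicate 2, and 64 and 19 without monocyte-derived replicates 1 and 3. The call of each gene named above was lost without HSC-derived replicate 1, with adjusted p from 0.0683 for S100a8 to 0.807 for Cd163, whose log2 change went from -1.24 to -0.17. The calls of Ngp (0.0745), Camp (0.0719), Ltf (0.0745), Ndufc1 (0.0908), Folr2 (0.191) and Tmem119 (0.137) were lost without replicate 2 as well. Without the shallow libraries Ngp (0.199), Camp (0.0745), Ltf (0.0959) and S100a8 (0.0922) were not called. The neutrophil list still tested higher (camera adjusted p = 1.44e-05), with a fitted median of 8.83 against 7.62 with all libraries. No member was called higher, and 1, Mmp9, named after its value was seen, was called lower (log2 change -1.01, adjusted p = 0.0308). Leaving out a single monocyte-derived library also ended the calls of Ngp (replicates 2 and 3), Cd163 (1, 2 and 3), Folr2 (1, 2 and 3), Ndufc1 (2, 3 and 4) and Pltp (1, 2 and 4). Apoe, Mrc1, Ms4a7, Clec12a, Ccr2, Cx3cr1, P2ry12 and Sall1 did not pass (adjusted p from 0.17 to 0.972).

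**Figure D4:**
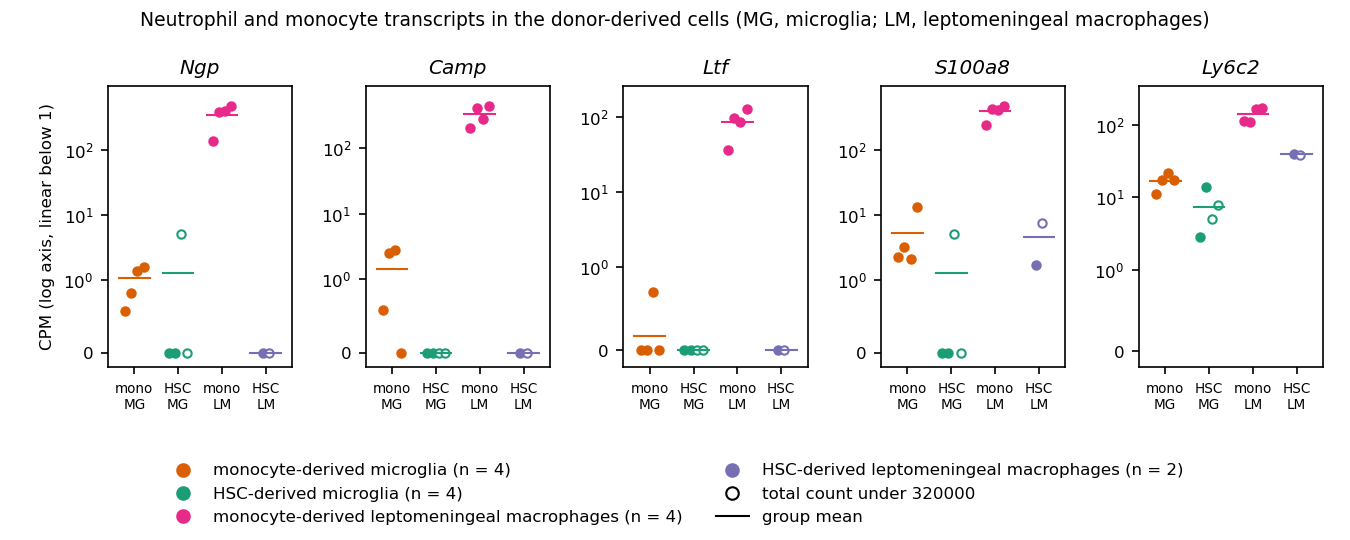
Expression of Ngp, Camp, Ltf, S100a8 and Ly6c2 in CPM (log axis, linear below 1) in the libraries of the 4 donor-derived groups; points are libraries, bars are group means and open points are libraries under 320000 counts. Ngp averages 344 CPM in monocyte-derived leptomeningeal macrophages and has 0 counts in the HSC-derived ones.

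The comparison of monocyte-derived leptomeningeal macrophages with monocyte-derived microglia asked how donor cells of 1 origin differed between compartments. Leptomeningeal macrophages expressed H2-Aa at 17800 ± 4980 CPM against 1350 ± 312 in microglia (n = 4 each) and Cd74 at 11600 ± 2280 against 1220 ± 244. F13a1 reached 959 ± 108 against 45.8 ± 7.2 CPM, Folr2 373 ± 78.1 against 13 ± 3.61, the lectin gene Clec10a 328 ± 22.2 against 11.2 ± 3.8, and Ccr2 499 ± 61.2 against 48 ± 6.98. P2ry12 was lower at 363 ± 176 against 1580 ± 115, Tmem119 at 216 ± 30.3 against 1060 ± 36.6 and Sall1 at 6.45 ± 3.05 against 31.4 ± 8.59. Clec12a, at 370 ± 48.2 against 345 ± 6.79 CPM, and Apoe, at 63000 ± 13600 against 84900 ± 4820, did not differ by the test (adjusted p = 0.688 and 0.161), while Ms4a7 fell by 0.70 on the log2 scale.

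Of 10597 genes 3736 passed (35.3%), 2012 higher and 1724 lower. The real split was the only 1 of 35 to call this many, and the highest other count was 0. Among the 10 highest were neutrophil granule genes: Ltf with a count ratio of 476 (95% interval 85 to 18800), Lcn2 with 338 (93.2 to 2800), Ngp with a log2 change of 8.20, Camp with 7.74, the gelatinase gene Mmp9 with 6.33 and S100a8 with 6.26. The others were the ficolin gene Fcna, with a ratio of 202 (55.5 to 1670), and Cd209f (6.59), Ptgds (6.26) and the phospholipase gene Pla2g2d (6.05). The lowest included the heat shock gene Hspa1b (-3.38), Tmem52 (-3.35), the matrix genes Npnt (-3.05) and Sparc (-2.79), the transcription factor gene Sox4 (-2.97), Cdk5r1 (-2.88), Cd34 (-2.65), the protease inhibitor gene Serpine2 (-2.62), the adhesion receptor gene Adgrg1 (-2.58) and the calpain gene Capn3 (-2.55).

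Homeostatic microglia genes fell, with 22 of 26 lower, 23 adjusted over the list alone (camera adjusted p = 2.52e-18, and adjusted p = 0.0176 with an estimated correlation). Border-associated macrophage genes rose with 23 higher and 2 lower of 28, 24 and 2 adjusted over the list alone (2.34e-18, and adjusted p = 0.00621 with an estimated correlation); Mrc1 doubled in CPM, from 597 ± 29.2 to 1190 ± 47.9. MHC class II genes rose with 9 of 12 higher, 10 adjusted over the list alone (4.63e-09, and adjusted p = 0.036 with an estimated correlation). Cell cycle genes rose with 11 of 16, 12 adjusted over the list alone (0.000242, and adjusted p = 0.036 with an estimated correlation), the replication clamp gene Pcna by a log2 change of 0.87. MHC class I genes were higher for 15 of 19 by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 6.32e-07, adjusted p = 0.064 with an estimated correlation), and interferon genes for 25 of 34, 26 adjusted over the list alone (3.64e-11, adjusted p = 0.052 with an estimated correlation). Ifitm3 was at 977 ± 123 against 130 ± 19.8 CPM. Of 26 inflammatory genes 21 were higher and 1 lower, 22 and 1 adjusted over the list alone (camera adjusted p = 1.35e-12, adjusted p = 0.0668 with an estimated correlation). The chemokine gene Ccl7 was at 672 ± 108 against 47.9 ± 10.8 CPM and the gene of the anti-inflammatory cytokine Il10 at 60.5 ± 13.2 against 5.73 ± 1.84. Immediate early genes had 19 higher and 4 lower of 25, 19 and 5 adjusted over the list alone (camera adjusted p = 6.42e-09, adjusted p = 0.13 with an estimated correlation). Egr1 was at 2740 ± 593 against 325 ± 31.5 CPM and Ier2 at 1090 ± 184 against 86.6 ± 7.37. Actinomycin D was used in the preparation of all groups, and the digestion differed between compartments. Complement, Fc and phagocytic receptor genes had 12 higher and 6 lower of 26, 14 and 7 adjusted over the list alone (camera adjusted p = 0.00938, adjusted p = 0.139 with an estimated correlation). The properdin gene Cfp was higher by a log2 change of 3.84. The cholesterol list did not pass (camera adjusted p = 0.593), with 7 higher and 6 lower of 19, 8 and 6 adjusted over the list alone; the efflux transporter gene Abca1 fell by 1.56.

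Markers of several other cells rose in the leptomeningeal libraries. All 17 monocyte genes were higher, as also when adjusted over the list alone (camera adjusted p = 1.34e-14, and adjusted p = 0.00621 with an estimated correlation). Lyz2 was at 12700 ± 3170 against 3900 ± 220 CPM outside that list and Ly6c2 at 138 ± 32.8 against 16.9 ± 4.44 in it. All 16 T and NK cell genes were higher, as also when adjusted over the list alone (6.2e-11, and adjusted p = 0.036 with an estimated correlation). Trac was at 51.7 ± 17.3 CPM. All 8 fibroblast and mural genes were higher, as also when adjusted over the list alone (6.47e-07, and adjusted p = 0.036 with an estimated correlation). The matrix gene Dcn, at 17.5 ± 4.53 CPM, was at least 33.7-fold higher. Neutrophil genes had 8 higher and 1 lower of 9, the same adjusted over the list alone (camera adjusted p = 1.9e-07, adjusted p = 0.052 with an estimated correlation). Dendritic cell genes had 5 and 2 of 9 by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.111 with an estimated correlation). Oligodendrocyte genes had 5 and 1 of 9, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00268, adjusted p = 0.178 with an estimated correlation), and astrocyte genes 5 and 1 of 8, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.193 with an estimated correlation). The B cell list did not pass (camera adjusted p = 0.253), with 3 of 5 higher by both adjustments, over all genes and adjusted over the list alone; Igkc had 389 ± 215 against 6.57 ± 6.38 CPM. Neuron (camera adjusted p = 0.686), erythroid (0.148) and endothelial genes (0.0659) did not pass either, with 0 of 5, 0 of 5 and 2 of 6 higher, the same adjusted over the list alone. Ribosomal protein genes rose with 58 of 62 by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 2.14e-27, adjusted p = 0.113 with an estimated correlation), at 13.7% to 14.6% of counts against 6.52% to 7.26%, with none of these 8 libraries shallow.

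The same comparison was made in HSC-derived cells, with 2 leptomeningeal libraries against 4 of microglia. H2-Aa reached 14400 ± 1350 CPM against 3840 ± 494 in microglia, F13a1 1360 ± 196 against 104 ± 22, Folr2 659 ± 4.4 against 22.9 ± 12.5, Mrc1 1790 ± 572 against 606 ± 57 and Ccr2 382 ± 148 against 109 ± 15.3. P2ry12 fell to 280 ± 58.3 from 1250 ± 226 CPM, Tmem119 to 91.7 ± 0.982 from 897 ± 170 and Cx3cr1 to 482 ± 6.06 from 1410 ± 294. The highest genes were Mgp, with a count ratio of 177 (95% interval 30.8 to 7110), Cd209f (log2 change 5.90), the hyaluronan receptor gene Lyve1 (5.82), the cystine transporter gene Slc7a11, with a ratio of 35.7 (8.98 to 310), and Mmp9 (5.60). The lowest were Whrn (-4.24), Rtn4rl1 (-3.73), Tmem52 (-3.70), Sparc (-3.47) and Npnt, with a ratio of 15.2 (5.09 to 74.9) in favour of microglia. Apoe fell by 1.27 on the log2 scale, and Clec12a and Ms4a7 did not pass (adjusted p = 0.426 and 0.125).

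Border-associated macrophage genes had 22 higher and 1 lower of 28, 24 and 1 adjusted over the list alone (camera adjusted p = 1.11e-41, and adjusted p = 0.000205 with an estimated correlation). Homeostatic microglia genes had 18 of 26 lower, 20 adjusted over the list alone (3.59e-25, and adjusted p = 0.00671 with an estimated correlation), and fibroblast and mural genes 5 of 8 higher, 7 adjusted over the list alone (4.57e-10, and adjusted p = 0.0166 with an estimated correlation). MHC class II genes had 7 higher and 1 lower of 12 by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 4.1e-08, adjusted p = 0.0776 with an estimated correlation). Interferon genes had 18 and 1 of 34, 19 and 1 adjusted over the list alone (6.8e-11, adjusted p = 0.0776 with an estimated correlation). Inflammatory genes had 12 higher of 26, and 17 higher and 2 lower adjusted over the list alone (1.11e-08, adjusted p = 0.154 with an estimated correlation). Ccl7 was at 886 ± 545 against 64.6 ± 9.68 CPM. Immediate early genes had 16 and 3 of 25, 17 and 3 adjusted over the list alone (1.03e-09, adjusted p = 0.154 with an estimated correlation). Egr1 was at 1670 ± 810 against 398 ± 90.8 CPM. Monocyte genes had 8 of 17 higher, 11 adjusted over the list alone (1.31e-06, adjusted p = 0.0546 with an estimated correlation), and T and NK cell genes 6 of 16, 12 adjusted over the list alone (6.5e-08, adjusted p = 0.0776 with an estimated correlation). MHC class I genes had 3 of 19, 6 adjusted over the list alone (0.000196, adjusted p = 0.163 with an estimated correlation), and complement, Fc and phagocytic receptor genes 9 higher and 4 lower of 26, 11 and 5 adjusted over the list alone (0.00893, adjusted p = 0.163 with an estimated correlation). Oligodendrocyte genes had 3 of 9 higher, 4 adjusted over the list alone (2.99e-05, adjusted p = 0.129 with an estimated correlation), and astrocyte genes 2 of 8, 5 adjusted over the list alone (0.000275, adjusted p = 0.129 with an estimated correlation). Ribosomal protein genes had 15 of 62 higher, 28 adjusted over the list alone (1.05e-18, adjusted p = 0.196 with an estimated correlation), and both groups held shallow libraries. Without the shallow libraries, which left 1 HSC-derived leptomeningeal library, the ribosomal list had a median log2 change of 1.04. The median in monocyte-derived cells in that fit was larger, at 1.46. The number of calls here also depends on the number and depth of the libraries, so it does not by itself measure the size of the change. Neutrophil genes (camera adjusted p = 0.358) and cell cycle genes (0.11) did not pass as lists, with 1 of 9, Mmp9, and 0 of 16 higher over all genes, and 1 higher and 1 lower, and 0, adjusted over the list alone.

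By the edgeR test 1030 genes passed (9.72%), 609 higher and 421 lower. The count was 366 without HSC-derived leptomeningeal replicate 1, where the calls of Npnt (0.144), Apoe (0.0907), Ly6c2 (0.215) and Sall1 (0.191) were lost, and Slc7a11 lost its call without replicate 2 (0.0531).

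The interaction asked whether the difference between monocyte-derived and HSC-derived cells changed with the compartment, with values relative to a median of 0.103 over all genes. The 6 genes that passed had a higher log2 difference in leptomeningeal macrophages than in microglia. They were H2-Eb1 (1.92 ± 0.32 SE, adjusted p = 0.0079), H2-Aa (1.81, 0.0308), Lgals3 (1.67, 0.0367), H2-Ab1 (1.59, 0.0367), the G protein gene Gngt2 (1.53, 0.0311) and Ccr2 (1.51, 0.0163). H2-Eb1 was lower in monocyte-derived than HSC-derived microglia, at 773 ± 168 against 2360 ± 370 CPM, while leptomeningeal macrophages had 10200 ± 1740 (n = 4) and 8200 ± 341 (n = 2). MHC class II genes had 3 of 12 higher, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.91e-11, adjusted p = 0.0541 with an estimated correlation). Disease-associated microglia genes had 1 of 22 higher, and 4 higher and 1 lower adjusted over the list alone (3.38e-06, adjusted p = 0.0541 with an estimated correlation), and monocyte genes 1 of 17, 2 adjusted over the list alone (1.99e-06, adjusted p = 0.0541 with an estimated correlation). No ribosomal protein gene passed over all genes and 16 were higher adjusted over the list alone (1.56e-20, adjusted p = 0.42 with an estimated correlation), in a comparison that held all 3 shallow libraries. Neutrophil (5.97e-10), inflammatory (0.000489), immediate early (0.00163), MHC class I (0.0193) and bone marrow-derived macrophage genes (0.0381) tested higher by camera with no member called over all genes; adjusted over the list alone, 2 immediate early genes were higher. With an estimated correlation, adjusted p = 0.0541, 0.551, 0.59, 0.551 and 0.551, and the bone marrow-derived list was also not called without the shallow libraries (0.13). By the edgeR test 6 genes were higher and 0 lower, with 846 at an unadjusted p under 0.05; DESeq2 called 49, 44 higher and 5 lower, and limma-voom 4. No call remained without HSC-derived leptomeningeal replicate 2, where adjusted p was 0.17 for H2-Eb1, H2-Aa, Gngt2 and Ccr2 and 0.277 for H2-Ab1 and Lgals3, and 40 genes passed, 32 higher and 8 lower, without replicate 1. Without monocyte-derived microglia replicates 1, 2 and 4 the counts were 1, 2 and 3, and without monocyte-derived leptomeningeal replicates 2, 3 and 4 they were 2, 1 and 3. H2-Eb1 was called in every other setting, and the other calls were lost without 1 or more other single libraries. Without the 3 shallow libraries 6 genes passed, of which 2 were among these 6, H2-Eb1 and Ccr2, and the MHC class II list had 1 call and the disease-associated list 0.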

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

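The tests of the 3 patterns weighed here were written only after the results had been seen, as were the list of choroid plexus markers and the Ttr level of 100 CPM; the tests of other splits of the libraries were planned. Single libraries far from the others of their group came from a Dixon test in groups of 4. It covered named genes, total counts, and the ribosomal protein, mitochondrial and Apoe shares of counts. In it 34 of 289 groups passed where chance would give about 1 in 20. Several of these are a few counts in 1 library with 0 in the others. Such a group passes however few the counts, so 1 in 20 does not hold for it.

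The first pattern is the lower level of MHC class II and ribosomal protein transcripts in monocyte-derived than in HSC-derived microglia. The shallow HSC-derived libraries as the whole cause of the MHC class II difference are argued against, since the median log2 change of the list was -0.56 without the 3 shallow libraries and -0.51 with them. The dendritic cell list was lower too without the shallow libraries, with a median of -0.94 and 1 of 12 called (camera adjusted p = 2.11e-05). Whether such cells among the sorted ones took part in the MHC class II difference was not tested. For the ribosomal protein genes the shallow libraries may account for most calls, since 11 of 50 were still called without them and the median of the 50 went from -1.04 to -0.45. HSC-derived microglia replicates 1 and 2, which are not shallow, still had fewer counts (691691 and 692884) than every monocyte-derived microglia library (1072911 or more). Whether lower depth was a cause cannot be decided by thinning, since drawing counts at random keeps each gene's expected share of counts. After all libraries were thinned to the same depth the median of the 54 genes was -1.09, against -1.07 before. What made the shallow libraries differ stays open.

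The second pattern is the higher level of p53 targets such as Cdkn1a in host than in donor-derived microglia, beside Ttr and 7 of 10 tested choroid plexus markers that were higher and 1 that was lower in host than in monocyte-derived microglia. RNA of choroid plexus cells as the whole cause of the Cdkn1a difference is argued against. The 3 donor-derived libraries with over 100 CPM of Ttr had a mean Cdkn1a excess of -9.04 CPM, where carry-over would have given 228. This was over the libraries of their group of like depth with less Ttr, a single library for each HSC-derived one. Over all others of the group the excess was 7.02, 112 and -135 CPM, where 116, 270 and 109 would have been seen. A partial contribution is not excluded, and other p53 targets were not tested in this way. Irradiation of the host cells cannot be told apart from host origin, with 9 of 24 p53 targets higher and 2 lower in host than in both donor-derived groups, because no host cells without irradiation were sequenced.

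The third pattern is the neutrophil granule transcripts such as Ngp and Camp in monocyte-derived but not HSC-derived leptomeningeal macrophages; Mmp9, also on the list, was present in both. Lower depth is argued against, as 244 Ngp counts would have been seen in the HSC-derived libraries at the level of the monocyte-derived ones, and 0 were. The fate label alone is argued against too, since 8 of 9 neutrophil genes were higher in these macrophages than in microglia with the same label. Neutrophil-lineage cells, or their RNA, among the sorted cells cannot be told apart from expression by the macrophages: all 8 of these genes were lowest in replicate 1, but so were 43 of 74 other genes with a log2 change of at least 4 over microglia, and that replicate also held more P2ry12, at 626 CPM against 275. Whether such cells would pass a gate on Cx3cr1-gfp stays open.

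In 4 comparisons only 1 of 35 splits, the real one, called as many genes. A chance division of the libraries is not excluded by this, since 1 of 35 is the smallest share such splits can give. The other splits also put libraries of both groups on each side, so that a real difference raised their spread and lowered their counts. The real and the highest other counts were 3201 and 0 for monocyte-derived against host microglia, 3114 and 1 for HSC-derived against host microglia, 200 and 0 for monocyte-derived against HSC-derived microglia, and 3736 and 0 for monocyte-derived leptomeningeal macrophages against microglia.

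Among host microglia, replicate 3 stood apart for Vnn3 (0.351 CPM against a mean of 0 in the others), Cd36 (0.351 against 0) and H2-Aa (55.8 against 32.3). Replicate 4 stood apart for Ahr (1.34 against 0) and Rps24 (1090 against 774), replicate 1 for Sall3 (96.6 against 78.2) and replicate 2 for Cmah (0.455 against 0).

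Among monocyte-derived microglia, replicate 1 stood apart for Ttr (157 CPM against 9.46), Lcn2 (1.15 against 0) and Mmp9 (0 against 2.33), and replicate 2 for Upk1b (15.7 against 7.69) and Lyz2 (4230 against 3790). Replicate 3 did so for Ltf (0.701 against 0), Fcna (1.4 against 0) and Igkc (16.1 against 3.39). Replicate 4 did so for Cx3cr1 (1890 against 1680), S100a8 (13.6 against 2.57) and Npnt (81.4 against 63.5).

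Among HSC-derived microglia, replicate 4 stood apart for Vnn3 (145 CPM against 50), Ctse (247 against 136), Ccr2 (86.1 against 116), Cxcl16 (481 against 419) and F13a1 (137 against 93.1). Replicate 1 did so for Mymk (8.5 against 0) and Phlda3 (2.83 against 0), and replicate 2 for B3galt5 (6.87 against 0), Mgp (1.37 against 0) and Slc7a11 (2.75 against 0).

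Among monocyte-derived leptomeningeal macrophages, replicate 1 stood apart for P2ry12 (626 CPM against 275), Adgrg1 (73.8 against 20.6), Capn3 (45.7 against 8.7) and Lgals3 (297 against 400), replicate 2 for Ms4a7 (567 against 451) and replicate 3 for Pltp (560 against 401).

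With all libraries in the fit, the edgeR interaction test called 6 genes. The log2 difference was 1.92 for H2-Eb1, 1.81 for H2-Aa, 1.67 for Lgals3, 1.59 for H2-Ab1, 1.53 for Gngt2 and 1.51 for Ccr2. These calls rested on 2 HSC-derived leptomeningeal libraries, 1 of them shallow, and depended on single libraries as given above. With only the libraries compared in the fit, 1 gene passed. As lists, ribosomal protein genes (camera adjusted p = 1.56e-20), MHC class II genes (1.91e-11), neutrophil genes (5.97e-10), monocyte genes (1.99e-06), disease-associated microglia genes (3.38e-06), inflammatory genes (0.000489), immediate early genes (0.00163), MHC class I genes (0.0193) and the bone marrow-derived macrophage list (0.0381) tested higher. None passed with an estimated correlation, where adjusted p ran from 0.0541 to 0.59, and the bone marrow-derived list was also not called without the shallow libraries (0.13).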

How the results depend on the processing

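The alternatives without the 3 shallow libraries and with thinned counts were chosen after the data had been seen; the others were planned. No call reversed under any alternative; the genes below that changed sign were not called with all libraries. Except where a construction is named, the cause was not tested. A threshold of at least 2-fold, which can only lower a count, left 1445 genes for monocyte-derived against host microglia, 1882 for HSC-derived against host, 93 for monocyte-derived against HSC-derived microglia and 1619 for monocyte-derived leptomeningeal macrophages against microglia, and 1082 genes shared by the donor-derived groups. Fitting only the libraries compared, which also changed which genes were tested, raised the counts for monocyte-derived against host microglia to 4179 and for compartment in monocyte-derived cells to 4069, and gave 2068 for HSC-derived against host microglia, 20 and 16 for origin in microglia and in leptomeningeal macrophages, 205 for compartment in HSC-derived cells and 1 for the interaction; the cause was not tested. limma-voom with quality weights gave 88 and 18 for origin in microglia and leptomeningeal macrophages, and DESeq2 gave 535 and 78, with 49 for the interaction. Without the shallow libraries the counts for origin were 50 and 72. Thinning counts to 150000 per library equalised depth but also left 4516 of 10597 genes to test, so that these 2 changes were not separated. It gave 745, 1083, 21, 1037 and 459 for monocyte-derived and HSC-derived against host microglia, origin in leptomeningeal macrophages, and compartment in monocyte-derived and HSC-derived cells. Of 182 list tests 86 passed camera, and 19 passed with an estimated correlation. Of the 86, fry called 64 in the same direction and did not do so for 22.

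With single libraries left out, counts ran from 31 to 555 for origin in microglia, 12 to 90 for origin in leptomeningeal macrophages, 366 to 1242 for compartment in HSC-derived cells and 0 to 40 for the interaction; those of the other comparisons stayed within 1.5-fold. A block on replicate number gave 2998, 2951, 238, 43, 3544, 1034 and 4 genes for the 7 comparisons, and of the interaction lists MHC class I and bone marrow-derived macrophage genes were not called with it (adjusted p = 0.0699 each). Same-number libraries were no more alike than others, with a median correlation of 0.0135 over 32 pairs against -0.007 over 96 other pairs. Each group was centred first, so that pairs with the 2 HSC-derived leptomeningeal libraries mirrored each other. Shared mice are not excluded by these medians.

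For origin in microglia the log2 change of Mrc1, -0.03 with all libraries, was 0.00 without a filter and -0.07 to 0.02 with single libraries left out, and Ms4a7, at -0.17, was 0.05 without the shallow libraries. For origin in leptomeningeal macrophages Clec12a, at 0.04, was -0.01 with DESeq2 size factors, -0.03 with the block, -0.04 with only the libraries compared, 0.00 with DESeq2, -0.02 thinned and -0.28 to 0.38 with single libraries left out. Apoe, at -0.11, was 0.01 without the shallow libraries and -0.20 to 0.03 with single libraries left out. P2ry12, at 0.34, was -0.05 without monocyte-derived replicate 1 and up to 0.70 without other single libraries.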

Other observations

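Clec12a had 459 ± 71.6 CPM in HSC-derived microglia and 380 ± 138 in HSC-derived leptomeningeal macrophages. It had 345 ± 6.79 CPM in monocyte-derived microglia and 370 ± 48.2 in monocyte-derived leptomeningeal macrophages, where P2ry12, Sall1 and Tmem119 fell by log2 changes of 2.12, 2.18 and 2.29. Sall1 was at 326 ± 10.7 CPM in host microglia, 31.4 ± 8.59 in monocyte-derived microglia and 6.45 ± 3.05 in monocyte-derived leptomeningeal macrophages.

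Further values were chosen after they had been seen and are given without a test. Nhlh2 and Xist also appear above in the comparisons with host microglia. Nhlh2 had 14700 and 17700 CPM in HSC-derived microglia replicates 3 and 4 and 12600 in HSC-derived leptomeningeal replicate 2, and Fbxo5 had 338, 172 and 293 in the same libraries. Xist had 75.4 ± 9.91 CPM in monocyte-derived microglia, 47.3 ± 5.48 in host microglia and 42 ± 4.28 in monocyte-derived leptomeningeal macrophages. Transcripts of mitochondrial genes made up 1.78%, 1.94% and 3.07% of counts in the 3 shallow libraries.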
